A study of Homo sapiens with 6 samples.

How the data were processed

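RNA sequencing libraries from human cells labelled as THP-1 were compared between 3 libraries labelled as given recombinant human RBP4 protein and 3 labelled as THP-1 alone, the control. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, messenger RNA was selected with poly-T beads and libraries were made with a NEBNext Ultra kit for Illumina sequencing, which does not mark the strand. Reads of genes that overlap on opposite strands, such as a gene and its antisense transcript, are therefore not separated, and KRT8 and KRT18 overlap in the annotation. Near-identical copies (HSPA1A and HSPA1B, HBA1 and HBA2, HBG1 and HBG2) can exchange reads, and their values are uncertain. The aligner, the read counter and their versions are not given in the sources used here.

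The authors deposited 1 table with a normalized signal per gene and library, the mean of each group, and their own comparison. Its log2 fold changes, p-values and adjusted p-values are the authors' own, per the file headers. In every library each deposited signal was a whole multiple of 1 step, as gene read counts divided by a size factor would be: 100% of the values were whole within a tolerance of 0.01 reads after division by the step. The steps equalled those of the median-of-ratios size factors that DESeq2 computes from the recovered reads. In control library 2 the step was 1.01, so close to 1 that an automatic test for recovered reads did not accept it, although all its values were whole multiples within the same tolerance. Recovered reads of this library, with those of the other 5, were used for depth and in the alternative tests on reads, never in the main test. All 28847 gene identifiers of the table had the same start and end as in GENCODE release 29 (GRCh38), and no coordinate was converted between builds. The authors' adjusted p-values equalled 1 for 10068 genes, and 1 gene had no p-value. No column of per-sample values was left unused (0 columns).

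The design fixed before the data were examined planned edgeR's quasi-likelihood test on counts and named limma-trend on log2(value + 1) for a table without counts. Because the table holds normalized values, limma-trend was the main test: genes with a value of at least 10 in at least 3 libraries were kept, log2(value + 1) was fitted with an intercept and the group, and variances were moderated with a trend and robustly (R 4.3.3, limma 3.58.1). Tests were two-sided, p-values were adjusted with the Benjamini-Hochberg method, and the threshold was 0.05. Fold changes are on the log2(value + 1) scale, which understates those of low genes. SE is the standard error of the log2 fold change. The gene lists, the alternatives and the rule for named genes were also fixed before the data were examined, and later additions are named as such. The test planned for counts, edgeR 4.0.16 with TMM scaling, called 7928 genes on the recovered reads, 4014 raised and 3914 lowered. Its use on recovered reads, as an alternative, was chosen after seeing the data. DESeq2 1.42.0 called 5967 genes, of which 5906 were also past the threshold in the authors' deposited table.

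A total of 36 gene lists were fixed: PI3K/AKT core, PI3K/AKT ligands and receptors, FOXO targets, M1 and M2 macrophage markers, NF-kB targets, interferon-stimulated genes, MHC class II, immune checkpoints, macrophage differentiation, undifferentiated myeloid genes, retinoid transport and retinoic acid targets, cell cycle, cholesterol biosynthesis, liver X receptor targets and lipid handling, integrated stress response, unfolded protein response, glycolysis and hypoxia, nuclear oxidative phosphorylation, lysosome, extracellular proteases, metallothioneins, NRF2 targets, immediate early genes, heat shock, mitochondrially encoded genes, ribosomal proteins, replication-dependent histones, and markers of squamous and epithelial, fibroblast, T and NK, B, endothelial, dendritic, neutrophil, and erythroid and platelet cells. The 29 lists with at least 5 tested genes were tested with limma's camera at a preset correlation between genes of 0.01, which compares a list with the other genes, adjusted over the lists. Of these, 15 passed, 9 upward and 6 downward. With a correlation estimated from the residuals 5 passed: integrated stress response, unfolded protein response, glycolysis and hypoxia, cell cycle and cholesterol biosynthesis. A further set of lineage lists for the identity of the cells was written after the data had been examined and before it was tested.

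Genes were named by 3 rules: the 10 raised and the 10 lowered genes with the largest log2 fold change among those past the threshold, with a mean of at least 5 CPM in the higher group and no overlap between the groups; up to 4 members of each list with the smallest p-values past the threshold, or the 2 most abundant where none passed; and a set of anchor genes of the PI3K/AKT pathway, of macrophage polarization and of RBP4 signalling whatever their values. Genes of the lineage lists and of the tests in the closing section are named outside these rules, after their values were seen. Some genes that the rules select are not reported here. CPM was computed from the deposited values, with the summed values of a library as its total.

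Between libraries of a group, a chi-square of the recovered reads over genes with at least 20 reads gave 1.82 to 2.24 per gene, and between groups 23.3 to 25.5, so no library repeated another within sampling noise. The biological coefficient of variation that edgeR estimated was 3.07%. Intervals and floors from read numbers cover counting error only.

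The procedure was tested on simulated counts drawn from the means of the real libraries, with 200 genes changed by known amounts and 15652 genes tested. In that simulated comparison limma-trend recovered 57.1% of genes changed 1.25-fold, 83.7% of those changed 1.5-fold, 93.9% of those changed 2-fold and 100% of those changed 4-fold, with 7 false calls (4.12% of calls). A lysosome list raised by 0.5 on the log2 scale was found, and 1 other list of 29 was called. The simulation drew genes independently and gave all of them 1 dispersion (0.001). It changed few genes, in both directions, whereas 50.6% of genes differed in the data. It therefore did not test the scaling or the correlation between genes. Alternatives covered the test (DESeq2, limma-voom, edgeR), the scaling (total reads, relative log expression, TMM), filters, the pseudocount (0.1 and 5), a threshold of 0.01, protein-coding genes alone, the replicate number as a block, each library left out in turn, and for lists the estimated correlation and fry. TMM scaling in limma-trend was also chosen after seeing the data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.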

Results

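Polyadenylated RNA was sequenced from 6 libraries labelled as THP-1, a human monocytic leukaemia line that is widely used to model macrophages. Of these, 3 were labelled as THP-1 alone and serve as the control, and 3 were labelled as THP-1 given recombinant human RBP4, the plasma carrier protein of retinol. The series presents the cells as a model of unpolarized (M0) macrophages and gives no dose or time. The deposited table listed 28847 genes with gene read counts divided by 1 size factor per library. Recovered from those values, the depth was 15672343, 16149118 and 15202000 reads in control libraries 1, 2 and 3, and 15994483, 16420517 and 16278627 reads in RBP4 libraries 1, 2 and 3. At that depth 3 reads, the upper limit that a count of 0 allows, corresponded to between 0.183 and 0.197 CPM (the value of a gene scaled to an equal total in each library). Reads above 0 were present for 23701 to 23996 genes in the control libraries and for 24620 to 24727 genes in the RBP4 libraries.

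The comparison asked which transcripts differed between the RBP4 and the control libraries, and in particular whether genes of the PI3K/AKT pathway and markers of M1-type polarization, both named in the title of the series, were among them. Genes of the integrated stress response and of the endoplasmic reticulum chaperone system rose in the libraries labelled RBP4. HSPA5, the main HSP70 chaperone of the endoplasmic reticulum, went from 13531 ± 201 to 40985 ± 207 normalized reads (mean ± SD, n = 3 per group), a 3.03-fold rise, and DDIT3, a transcription factor of the stress response, from 396 ± 24.1 to 1918 ± 48.1, a 4.84-fold rise. Genes of glycolysis fell: LDHA, which converts pyruvate to lactate, went from 43551 ± 129 to 15649 ± 150 normalized reads (2.78-fold lower), and PGK1, a glycolytic kinase, from 19443 ± 315 to 7835 ± 120 (2.48-fold lower). INSIG1, which holds back cholesterol synthesis and is itself induced by the factors that drive it, fell 2.97-fold, and BUB1, a kinase of the mitotic checkpoint, fell 2.61-fold. AKT1 was 1.17-fold lower, whereas the PI3K/AKT core list as a whole and the M1 list did not pass their tests.

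Of 15676 genes tested, 7934 (50.6%) differed at an adjusted p under 0.05 in limma's moderated test with Benjamini-Hochberg adjustment, 3838 of them raised and 4096 lowered in the RBP4 libraries. An unadjusted p under 0.05 was reached by 8764 genes. At least a 2-fold change was found for 923 genes, 696 raised and 227 lowered, a count that depended on the filter (1518 genes without one, 234 at 5 CPM or more in 3 libraries), on the genes kept (590 among protein-coding genes) and on the pseudocount (610 with 5). The median log2 fold change was 0.48 among the raised and -0.27 among the lowered genes. The values of the groups did not overlap for 8809 of the genes tested (56.2%), where chance alone would give 10%. The first principal component held 63.1% of the variance and separated the groups, and the second held 11.2%. Raised genes made up 48.4% of the calls with the authors' size factors and 61.7% when the libraries were scaled to their total reads, which moved the median log2 fold change of all genes by 0.068. The authors' deposited table held 5931 genes at an adjusted p under 0.05, 2734 raised and 3197 lowered. Of these, 5836 were tested here and 5828 were called in the same direction as in the authors' deposited table.

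Most genes of the monocyte and macrophage lineage list were near 0 in the libraries of both groups. Of its 24 genes, 4 (CD33, SPI1, FCGR2A and CTSS) reached 10 CPM in all 6 libraries, which is 16.7%, and the median of the list lay between 0.0929 and 0.335 CPM per library. These values count genes not analysed as 0 CPM. The 21 genes analysed had a median of 0.272 CPM. CD14, the co-receptor for lipopolysaccharide on monocytes, had 1.39 ± 0.647 normalized reads in the control libraries and 0 in all 3 RBP4 libraries, and CD68, a lysosomal protein of macrophages, had 0.345 ± 0.598 and 1.27 ± 0.55. Of 26 genes of the erythroid lineage, 20 (76.9%) reached 10 CPM in all 6 libraries, with a median between 49.9 and 57.6 CPM per library. GATA1, the main transcription factor of red cell precursors, stood at 195 ± 5.51 CPM in the control and 209 ± 1.72 CPM in the RBP4 libraries, and RHAG, a membrane protein of red cells, at 470 ± 3.17 and 552 ± 11.2 CPM. Chosen after their values were seen, TFRC, the transferrin receptor, fell from 901 ± 15.4 to 483 ± 15.0 CPM (adjusted p = 1.7e-44) and EPOR, the erythropoietin receptor, rose by 0.96 on the log2 scale to 36.7 ± 1.09 CPM (adjusted p = 1.3e-18). The leukocyte gene PTPRC stood at 292 ± 4.19 and 307 ± 5.29 CPM, and 6 of 8 pan-leukocyte genes reached 10 CPM in all 6 libraries. These levels go against the label of a monocytic line, so the groups are named throughout by their labels. The share of reads from mitochondrially encoded genes also moved with the group, from between 5.90% and 6.10% in the control libraries to between 7.58% and 7.69% in the RBP4 libraries.

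**Figure D1:**
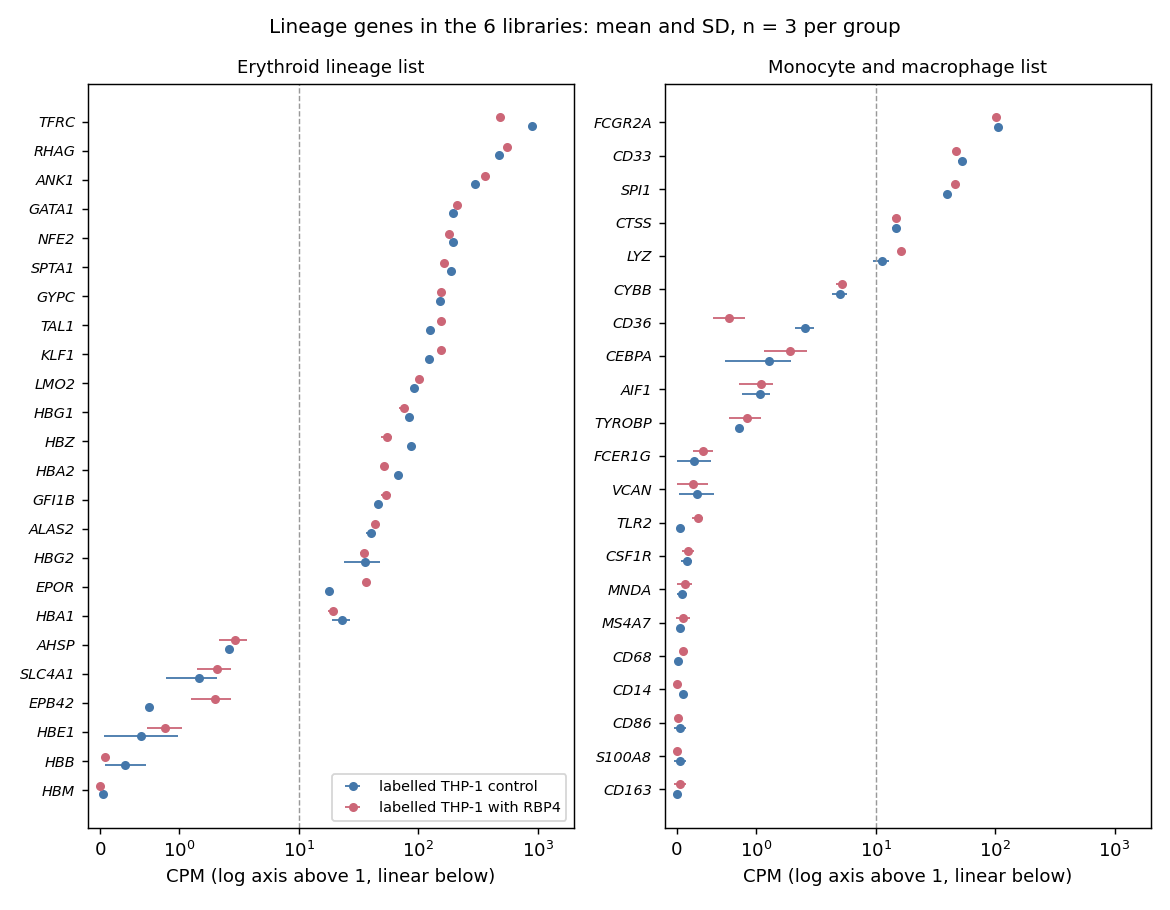
CPM of the genes of the erythroid list (left) and of the monocyte and macrophage list (right) in the libraries labelled control and RBP4, on an axis that is linear below 1 CPM and logarithmic above; points are means and bars SDs of 3 libraries, and the dashed line marks 10 CPM. Of the 24 erythroid genes drawn, 18 lie at or above that line in all 6 libraries, as do 4 monocyte and macrophage genes.

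All 26 tested genes of the integrated stress response, the programme that cells switch on when translation initiation is restrained, rose in the RBP4 libraries, with a median log2 fold change of 0.94 (camera adjusted p = 2.7e-18; adjusted p = 0.0152 with an estimated correlation). CHAC1, which degrades glutathione, rose 7.26-fold, from 146 ± 6.62 to 1063 ± 51.9 normalized reads (n = 3 per group; log2 fold change 2.86, SE 0.074, adjusted p = 3.0e-44). ATF5 rose 5.42-fold, TRIB3, a pseudokinase that binds AKT, 3.60-fold, and SESN2, an inhibitor of mTORC1, 2.92-fold. Of 21 tested genes of the unfolded protein response, 19 rose, none fell and 2 did not pass, with a median of 0.72 (camera adjusted p = 9.8e-11; adjusted p = 0.0185 with an estimated correlation). HSPA5 (ENSG00000044574, chromosome 9, 125234853 to 125241330 on GRCh38) had a log2 fold change of 1.60 (SE 0.020, adjusted p = 4.3e-63), and HERPUD1, a component of endoplasmic reticulum associated degradation, rose 3.38-fold. DDIT3 (ENSG00000175197, chromosome 12, 57516588 to 57521737) had a log2 fold change of 2.28 (SE 0.053, adjusted p = 6.5e-47).

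Glycolysis and hypoxia genes moved the other way. Of 32 tested, 29 fell, 1 rose and 2 did not pass, with a median log2 fold change of -1.09 (camera adjusted p = 1.5e-17; adjusted p = 0.0185 with an estimated correlation). LDHA (ENSG00000134333, chromosome 11, 18394388 to 18408425) had a log2 fold change of -1.48 (SE 0.020, adjusted p = 6.3e-62). GPI fell 2.14-fold, GAPDH 1.79-fold and EGLN3, an oxygen-sensing hydroxylase that hypoxia induces, 3.12-fold. The member that rose was VEGFA, the vascular growth factor, from 5280 ± 164 to 6254 ± 136 normalized reads. Among the 13 mitochondrially encoded genes, 11 rose and 2 fell (0 with the libraries scaled to total reads), with a median of 0.42 (camera adjusted p = 9.5e-05; adjusted p = 0.129 with an estimated correlation). MT-ND2, a subunit of respiratory complex I, rose 1.52-fold and MT-CO2, a subunit of cytochrome c oxidase, 1.46-fold. Of 36 nuclear genes of oxidative phosphorylation, 31 fell (32 when adjusted over the list alone), none rose and 5 did not pass, with a median of -0.21 (camera adjusted p = 3.6e-08; adjusted p = 0.104 with an estimated correlation). ATP5F1B, a subunit of ATP synthase, fell from 22800.4 ± 92.2 to 19323 ± 152 normalized reads. The nuclear list had a median of 111 CPM in the control libraries. Of all protein-coding genes of about that abundance (averaging 1483 to 5686 normalized reads), 61.4% fell, with a median of -0.14. The list test did not adjust for abundance. Except where another value stands beside them, counts adjusted over the list alone equalled those adjusted over all genes tested.

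**Figure D2:**
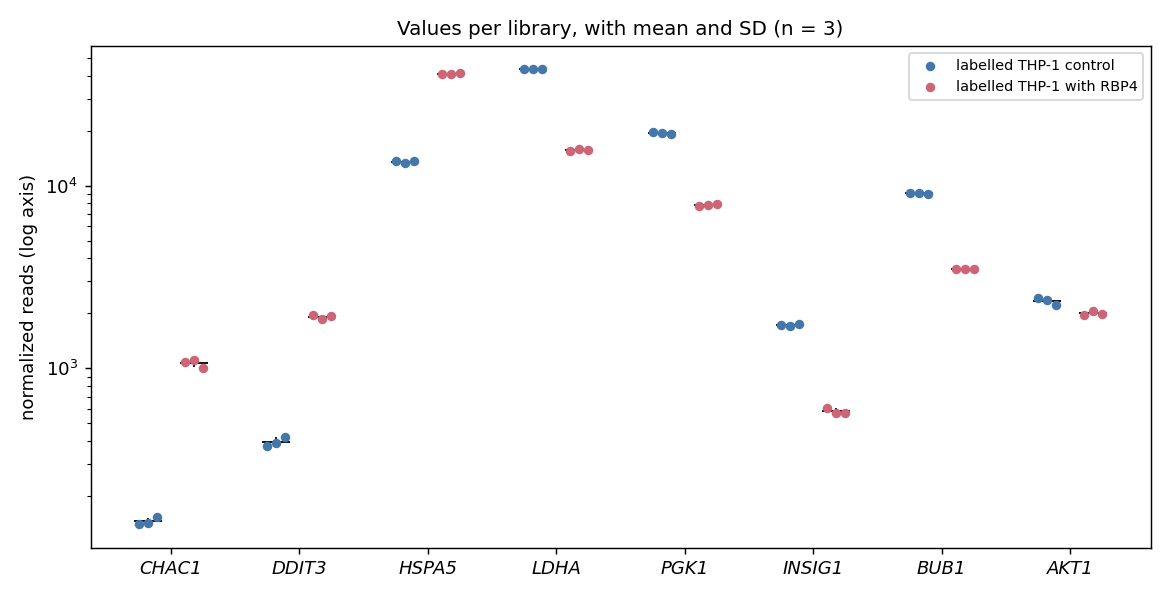
Normalized reads on a logarithmic axis for 8 genes in each library labelled control (blue) or RBP4 (red); each point is 1 library, and the horizontal and vertical marks give the mean and SD of 3 libraries. The groups of CHAC1, DDIT3, HSPA5, LDHA, PGK1, INSIG1 and BUB1 lie apart by 2.48-fold or more, and those of AKT1 by 1.17-fold.

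Genes of cholesterol synthesis and of the cell cycle fell as groups. Of 24 cholesterol genes, 20 fell, 1 rose and 3 did not pass, with a median log2 fold change of -0.35 (camera adjusted p = 5.6e-08; adjusted p = 0.0185 with an estimated correlation). MSMO1, a sterol oxidase, fell 2.81-fold and FDFT1, which makes squalene, 1.78-fold. Of 41 cell cycle genes, 31 fell, 1 rose (3 with the libraries scaled to total reads) and 9 did not pass, with a median of -0.26 (camera adjusted p = 1.9e-08; adjusted p = 0.0185 with an estimated correlation). CCNB1, the mitotic cyclin B1, fell 1.48-fold and MCM7, a subunit of the replicative helicase, 1.36-fold. BUB1 stood further from 0 than these, with a log2 fold change of -1.38 (SE 0.028, adjusted p = 1.0e-50). The cell cycle list had a median of 119 CPM in the control libraries, and protein-coding genes of about that abundance fell as a whole. Of 2065 averaging 1483 to 5686 normalized reads, 1267 (61.4%) fell and 288 rose, with a median of -0.14. The list test did not adjust for abundance. Among 20 genes of lipid handling and liver X receptor targets, 7 rose and 9 fell (10 when adjusted over the list alone), and the list did not pass (median -0.13, camera adjusted p = 0.276). Its lowered members included the enzymes of fatty acid synthesis FASN and SCD, which fell 1.80-fold and 1.78-fold.

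The PI3K/AKT pathway relays signals from growth factor receptors through lipid kinases to the AKT kinases. Of the 35 tested genes of its core list, 10 rose, 14 fell and 11 did not pass. The camera test did not set the list apart from the other genes (direction down, adjusted p = 0.496), and its median of -0.026 and mean of 0.00089 differed in sign. With the libraries scaled to total reads, the median was 0.042, with 12 genes raised and 12 lowered. AKT1 (ENSG00000142208, chromosome 14, 104769349 to 104795751) went from 2340 ± 105 to 2002 ± 57.8 normalized reads (n = 3 per group; log2 fold change -0.22, SE 0.038, adjusted p = 7.9e-07), and AKT2 fell 1.15-fold. Among the catalytic subunits of PI3K, PIK3CA fell 1.21-fold and PIK3CG 1.42-fold, while PIK3CD stood at 1372 ± 38.8 and 1359 ± 72.1 normalized reads (adjusted p = 0.82). SGK3, a kinase related to AKT, rose 1.68-fold. Of 45 tested ligands and receptors that feed the pathway, 21 rose, 8 fell and 16 did not pass (median 0.18, camera adjusted p = 0.0151; adjusted p = 0.123 with an estimated correlation). CSF3R, the receptor for granulocyte colony-stimulating factor, rose 4.16-fold and the matrix protein gene FN1 1.42-fold. Of the 66 ligand and receptor genes analysed, 45 were tested and 20 reached 10 CPM in all 6 libraries. The 66 had a median of 2.24 CPM in the control libraries, and protein-coding genes of low abundance rose as a whole. Of 1469 averaging 26.3 to 101 normalized reads, 561 rose and 106 fell (median 0.30). Of 2680 averaging 101 to 387, 948 rose and 338 fell (median 0.10). Among genes at 5 CPM or more in 3 libraries the list also passed (camera adjusted p = 0.00789). Neither list test adjusted for abundance, so neither sets the list apart from this trend.

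**Figure D3:**
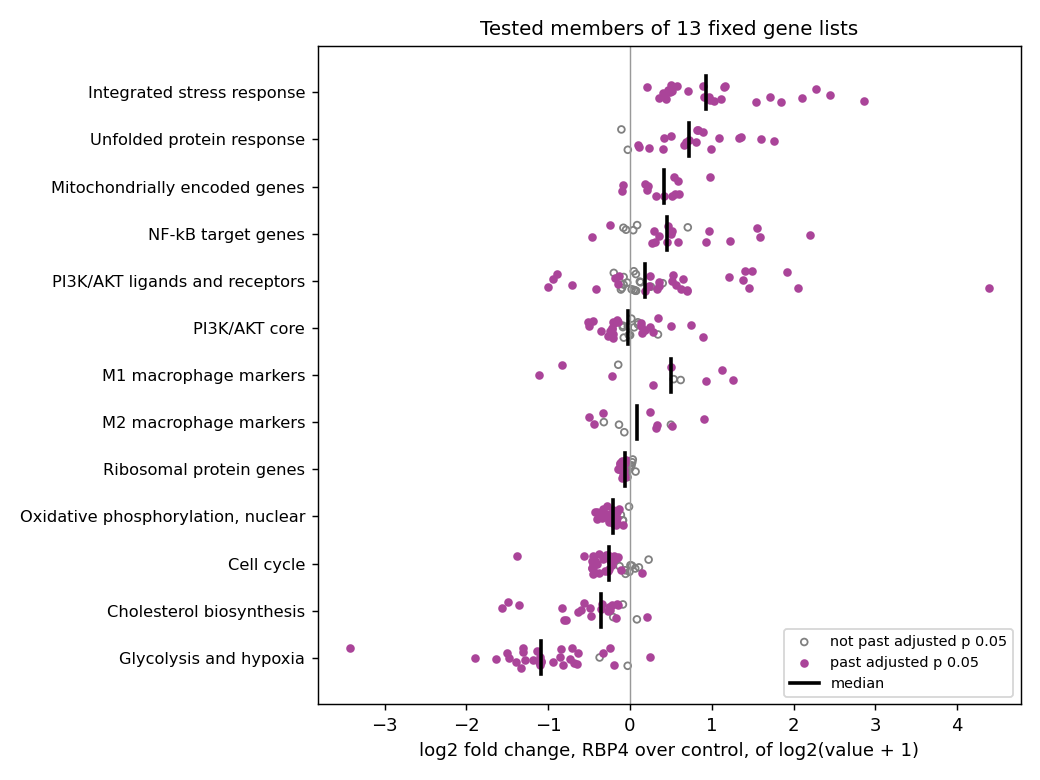
Log2 fold change of RBP4 over control libraries for the tested members of 13 gene lists; each point is 1 gene, filled where it passed an adjusted p of 0.05, and the vertical bar is the median of the list. The median was 0.94 for the integrated stress response, -1.09 for glycolysis and hypoxia and -0.026 for the PI3K/AKT core; this last median was 0.042 with the libraries scaled to total reads.

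Most markers of polarized macrophages were not tested, being too low or not analysed here, in libraries where most genes of the monocyte and macrophage lineage list were near 0. Of 39 M1 markers, 31 were analysed and 11 passed the filter and were tested, of which 5 rose, 3 fell and 3 did not pass (median log2 fold change 0.50, camera adjusted p = 0.528). IL23A, a cytokine subunit, went from 43.6 ± 2.16 to 106 ± 5.29 normalized reads, a 2.40-fold rise, and the co-stimulatory receptor gene CD40 rose 2.18-fold. KYNU, an enzyme of tryptophan breakdown, fell 2.16-fold and SOCS3, a feedback inhibitor of cytokine signalling, 1.78-fold. CD80, a co-stimulatory ligand, stood at 58.4 ± 17.5 and 80.5 ± 9.20 normalized reads (adjusted p = 0.022). The CD80 call was lost without control library 3, where its log2 fold change dropped from 0.50 to 0.23 (adjusted p = 0.306), without RBP4 library 2 (0.099) or RBP4 library 3 (0.0639), and with DESeq2 (0.165), in a range of 0.00541 to 0.306 over its alternatives. TNF had 1.03 ± 1.04 and 0.967 ± 1.67 normalized reads and IL6 had 1.72 ± 2.16 and 5.37 ± 6.95, and neither was tested. Of 42 M2 markers, 24 were analysed and 12 were tested, of which 5 rose, 3 fell and 4 did not pass (median 0.088, camera adjusted p = 0.582). TGFB1, an anti-inflammatory cytokine, fell 1.36-fold and TGM2, a transglutaminase, rose 1.24-fold. The macrophage scavenger and mannose receptors CD163 and MRC1 had means below 1 normalized read in each group and were not tested. ITGAM, an integrin of myeloid cells, went from 104 ± 11.4 to 168 ± 24.2 normalized reads, a 1.61-fold rise.

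Targets of NF-kB, the transcription factor family of inflammatory signalling, were mostly raised. Of 22 tested, 15 rose, 2 fell and 5 did not pass (median log2 fold change 0.46, camera adjusted p = 0.00132; adjusted p = 0.129 with an estimated correlation). TNFAIP3, a feedback inhibitor of NF-kB, rose 2.93-fold, from 139 ± 22.2 to 405 ± 12.9 normalized reads, and BIRC3, an inhibitor of cell death, 2.33-fold. TNIP1, a partner of the TNFAIP3 protein, fell 1.38-fold. Of 31 interferon-stimulated genes, 13 rose (14 when adjusted over the list alone), 4 fell and 14 did not pass (median 0.37, camera adjusted p = 0.0272; adjusted p = 0.349 with an estimated correlation). That call was also lost without control library 2 (adjusted p = 0.0557) or RBP4 library 2 (0.0534), with scaling to total reads (0.0898) and among genes at 5 CPM or more in 3 libraries (0.152), in a range of 0.00818 to 0.349 over its alternatives. IFI35 rose 2.01-fold and EPSTI1, another gene that interferon induces, fell 2.11-fold. Of 9 immune checkpoint and anti-phagocytic genes, 5 rose (6 when adjusted over the list alone), none fell and 4 did not pass (median 0.42, camera adjusted p = 0.0173; adjusted p = 0.129 with an estimated correlation). VSIR, which encodes the checkpoint protein VISTA, rose 3.08-fold, from 87.4 ± 18.8 to 269 ± 34.5 normalized reads. In the control libraries the members analysed had medians of 2.10 (NF-kB), 1.54 (interferon) and 3.90 CPM (checkpoint genes). These medians include members too low to be tested, so those of the tested members were not given by them. Of the members analysed, 11 of 34 (NF-kB), 4 of 40 (interferon) and 4 of 12 (checkpoint genes) reached 10 CPM in all 6 libraries. Protein-coding genes of low abundance rose as a whole, and these list tests did not adjust for abundance. Among genes at 5 CPM or more in 3 libraries, the NF-kB and checkpoint lists also passed (camera adjusted p = 0.0113 and 0.0335).

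Retinoid transport genes and retinoic acid targets did not move as a group. Of 16 tested, 7 rose, 5 fell and 4 did not pass, and the median log2 fold change of 0.12 and the camera direction (up, adjusted p = 0.704) differed in sign from the mean of -0.081. ALDH1A2, which makes retinoic acid, fell 1.58-fold, DHRS3, a retinal reductase that retinoic acid induces, fell 1.75-fold, and ALDH1A1 rose 1.38-fold. STRA6, the cell surface receptor for RBP4, had 52.5 ± 8.16 and 41.4 ± 9.41 normalized reads (adjusted p = 0.16). The RBP4 and TLR4 genes were not analysed here.

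Among single genes, those with the largest changes in each direction by the fixed rule included members of no list. SLC22A15, a membrane transporter of organic ions, rose from 3.44 ± 1.12 to 85.3 ± 4.84 normalized reads (n = 3 per group; log2 fold change 4.32, SE 0.32, adjusted p = 5.1e-19). TMEM154 rose from 10.4 ± 2.12 to 190 ± 3.85, a 17.0-fold rise, UNC5B, a netrin receptor, 6.96-fold, and INHBE, which encodes an activin subunit, 5.61-fold. MS4A4A, a membrane protein known from macrophages, fell from 2699 to 580 normalized reads (n = 3 per group; log2 fold change -2.22, SE 0.045, adjusted p = 2.2e-50), and its neighbour on chromosome 11, MS4A6A, fell 4.04-fold. SLC6A8, the creatine transporter, fell 3.04-fold, and ACPP, an acid phosphatase, 5.01-fold.

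The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. All libraries of a group share 1 treatment label, and no library separates the treatment from other differences between the cultures.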

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

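The use of the edgeR test with TMM on the recovered reads and TMM scaling in limma-trend were chosen after the result was seen. The edgeR test with TMM itself had been planned for counts, and the other alternatives were planned. The number of changed genes (7934) ranged from 5967 with DESeq2 to 7999 without a filter, and no gene called in both changed direction in any of the 21 alternatives. Genes changed at least 2-fold (923) numbered 1518 without a filter, 234 at 5 CPM or more in 3 libraries and 590 among protein-coding genes, as other genes were tested, and 610 with a pseudocount of 5, which pulls low genes to 0. Leaving out 1 library gave 7044 to 7521 changed genes, 3329 to 3647 raised, 3701 to 3874 lowered and 882 to 946 at least 2-fold, and 12 to 15 lists called.

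Replicate numbers do not pair the libraries (correlations of deviations 0.0037, -0.0079 and -0.017, none correlating best with its own number); with the replicate number as a block 7829 genes were called and no call of a named gene or list was lost or gained.

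Of 15 lists called, 5 kept their call with an estimated correlation; fry, which does not compare a list with other genes, called 21, among them PI3K/AKT core (adjusted p = 0.0254, down) and M2 markers (0.0128, up). The M1 direction turned at 5 CPM or more (adjusted p = 0.615; not called either way); the cause was not tested. Scaling to total reads ended the call of ribosomal protein genes (0.467). NRF2 targets (0.0541) passed with that scaling (0.0278), at 5 CPM or more (0.0141), without a filter (0.0470), without RBP4 library 1 (0.0440) and with fry (0.000323).

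Named genes were run with DESeq2, edgeR with TMM, the scalings, the block and each library left out, not with the other alternatives. Of 143 named genes tested, 134 kept direction and call with DESeq2, 137 with scaling to total reads and all 143 with TMM scaling, edgeR and the block. No gene that turned was called: PIK3R1 (0.042 with scaling to total reads, -0.113 to 0.0596 over left-out libraries) and PIK3CD (0.054, -0.0458 to 0.0291); the cause was not tested. CXCL10 passed only without control library 3 (log2 fold change 0.90 against 0.62, adjusted p = 0.0496). Leaving out 1 library also ended the calls of PLAU (control 1 or 3, RBP4 2 or 3), SLC30A1 (each but control 1), HIST1H2AG (control 2 or 3, RBP4 2), KRT13 (control 1 or 2, RBP4 1 or 3), KRT18 (control 3, RBP4 3), COL1A2 and CD3D (control 3, RBP4 1), HBA1 (control 2) and PECAM1 (RBP4 3); all of these but HBA1, and CD80, also lost their call with DESeq2. In that order, the highest adjusted p over the alternatives run for named genes was 0.132, 0.208, 0.314, 0.152, 0.380, 0.0907, 0.118, 0.0720 and 0.109. Depth limits genes near the floor of 3 reads, 0.197 CPM in the shallowest library.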

Other observations

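Of the tests on the patterns weighed here, those of cell identity, depth, mislabelling, gene length, culture and genomic DNA were chosen after the result was seen. Of 16 immediate early genes, 10 rose, 2 fell (1 with the libraries scaled to total reads) and 4 did not pass (median log2 fold change 0.20, camera adjusted p = 0.0105; adjusted p = 0.129 with an estimated correlation), with ATF3, also a stress-response factor, up 3.28-fold and FOS, part of the AP-1 factor, up 2.91-fold. Of 18 NRF2 targets, genes of the antioxidant response, 10 rose, 4 fell and 4 did not pass (median 0.11, camera adjusted p = 0.0541), but with scaling to total reads 12 rose and 1 fell (median 0.17, adjusted p = 0.0278). Raised members included OSGIN1, up 4.99-fold, and the cystine transporter gene SLC7A11, up 2.24-fold. Heat shock genes split, 4 raised, 6 lowered and 2 not past the test. Their median of -0.076 and the camera direction (down, adjusted p = 0.765) differed in sign from their mean of 0.22: HSP90AA1, a cytosolic chaperone, fell 1.76-fold while DNAJB1, a co-chaperone, rose 1.73-fold. Fry called the heat shock list in the other direction (up, adjusted p = 0.0178), and with scaling to total reads its median was -0.0076. Of 21 FOXO targets, 8 rose, 4 fell and 9 did not pass (median 0.093, camera adjusted p = 0.496). Of 30 lysosomal genes, 11 rose (10 when adjusted over the list alone, 18 with the libraries scaled to total reads), 4 fell (2 with that scaling) and 15 did not pass (median 0.036, camera adjusted p = 0.271), with NEU1, a sialidase, raised by 0.59 on the log2 scale. Of 32 ribosomal protein genes, 18 fell, none rose and 14 did not pass (median -0.066, camera adjusted p = 0.0273; adjusted p = 0.596 with an estimated correlation), but with scaling to total reads the median was 0.0027 and 2 rose and 2 fell (adjusted p = 0.467). The ribosomal call was also lost among genes at 5 CPM or more in 3 libraries (0.126), with fry (0.0683), and without control library 2 (0.0817), RBP4 library 1 (0.105) or RBP4 library 2 (0.0728), in a range of 0.00387 to 0.596. The ribosomal list had a median of 1018 CPM in the control libraries, and protein-coding genes of about that abundance fell further. Of 329 averaging 5686 to 21794 normalized reads, 229 (69.6%) fell and 47 rose, with a median of -0.16.

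Of 9 extracellular protease and matrix genes, 4 rose, none fell and 5 did not pass (median 0.27, camera adjusted p = 0.0403; adjusted p = 0.220 with an estimated correlation), a call lost without control library 2 (0.0883), control library 3 (0.105) or RBP4 library 2 (0.0538), in a range of 0.00505 to 0.220. ADAM8, a metalloprotease of leukocytes, rose 1.20-fold. Of the 18 protease and matrix genes analysed, 9 were tested and 4 reached 10 CPM in all 6 libraries. The 18 had a median of 0.999 CPM in the control libraries, and protein-coding genes of low abundance rose as a whole. Among genes at 5 CPM or more in 3 libraries the list also passed (camera adjusted p = 0.0386). Among 19 macrophage differentiation genes 9 rose, 6 fell and 4 did not pass (median 0.17, camera adjusted p = 0.528), and CD36, a scavenger receptor, fell 3.86-fold from 41.6 ± 7.55 to 10.2 ± 3.02 normalized reads (n = 3 per group). Among 10 undifferentiated myeloid genes 2 rose, 6 fell and 2 did not pass (median -0.19, camera adjusted p = 0.151), with MYC, a growth-promoting transcription factor, down 1.37-fold and MS4A3, a gene of granulocyte and monocyte precursors, down 1.79-fold. Of 5 MHC class II genes 1 rose, RFX5, and 4 did not pass (median 0.14, camera adjusted p = 0.496). Of 7 histone genes 1 rose, 1 fell (0 with the libraries scaled to total reads) and 5 did not pass (median 0.025, camera adjusted p = 0.765). Of 6 erythroid and platelet markers 2 rose, 2 fell and 2 did not pass (median -0.093, camera adjusted p = 0.983), with ITGA2B, a platelet integrin, up 1.62-fold. Of 5 squamous and epithelial markers, 4 fell and 1 did not pass (median -0.33, camera adjusted p = 0.0272; adjusted p = 0.245 with an estimated correlation), among them the keratin gene KRT8, down 1.26-fold, and EPCAM, down 1.54-fold. Lists with fewer than 5 tested genes had no list test: metallothioneins (2 tested, 1 raised, the zinc exporter gene SLC30A1), fibroblast (2 tested, 1 raised and 1 lowered), T and NK (3 tested, 2 lowered), B cell (1 tested, none past the test), endothelial (3 tested, 2 lowered, EGFL7 by 2.32-fold), dendritic (3 tested, 2 raised, LAMP3 by 2.16-fold) and neutrophil markers (2 tested, CSF3R raised).

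Most genes of the monocyte and macrophage lineage list were near 0 in all 6 libraries, against their label: 14 of 24 were under 1 CPM in all 6 or not analysed. Others were not low, with FCGR2A of that list at 105 CPM and MS4A4A, known from macrophages, at 166 CPM in the control libraries. Of the 28 genes analysed of the macrophage differentiation list, fixed beforehand, 10 reached 10 CPM in all 6 libraries. Their median was 2.86 CPM in the control libraries. A limit of depth was argued against, since 3 reads correspond to 0.197 CPM in the shallowest library, and so was a single mislabelled library as the source, since in 6 of 6 libraries the median of the erythroid list lay above that of the monocyte and macrophage list; an exchange of labels between the groups was not tested. The values are in line with the hypothesis that all 6 libraries hold another cell type, with an erythroid profile: 76.9% of the 26 erythroid genes reached 10 CPM in all 6 libraries against 16.7% of the monocyte and macrophage genes, with TFRC (901 ± 15.4 CPM in the control libraries), RHAG (470 ± 3.17) and ANK1 (300 ± 1.78) the most abundant, while HBB stood at 0.322 ± 0.256 CPM. Of the 26, 7 are also used by other blood cells (a choice made after their levels were seen), 0 stand in another lineage list and 5 in the fixed erythroid and platelet list; of the 19 left, 13 (68.4%) reached 10 CPM in all 6 libraries. Apart from the pan-leukocyte list (75%), the largest share of the other lineage lists was 25% (squamous and epithelial). Next came 14.3% for a monocytic leukaemia programme, 12.5% for megakaryocytes and 10% for granulocyte precursors. All these lists were written after the file was seen. None of the genes analysed of the T and NK, B, fibroblast, endothelial, hepatocyte or neural lists reached 10 CPM in all 6 libraries. All shares count genes not analysed as 0 CPM, so they are lower limits. All 26 erythroid genes were analysed, but 21 of 24 monocyte and macrophage and 3 of 7 leukaemia programme genes. So were 3 of 8 megakaryocyte, 7 of 14 T and NK and 1 of 8 neural genes. EGFL7 of the fixed endothelial list, which the lineage lists leave out, stood at 352 ± 11.4 CPM in the control and 159 ± 6.21 CPM in the RBP4 libraries. For the low monocyte genes, no biological explanation other than cell identity was tested, since the design names no group that would give one.

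Glycolysis genes were lower and stress-response genes higher in the libraries labelled RBP4, by medians 2.02 apart on the log2 scale. GC content and gene length were argued against as the whole source of this gap, which stayed at 1.98 after the trend on GC was removed and at 2.00 after that on length. A difference between the cultures remains open, such as less glucose in those labelled RBP4, which is known to lower TXNIP and ARRDC4 and to raise HSPA5: TXNIP fell by 1.38 and ARRDC4 fell by 0.77 on the log2 scale (adjusted p = 7.9e-48 and 1.6e-10), and no library separates the treatment from culture conditions. Lower activity of hypoxia-inducible factor may also contribute: its targets outside the fixed lists, chosen after the fall of other hypoxia genes had been seen but with their own values unseen, had a median of -0.44, with 7 of 10 lowered, 1 raised and 2 not past the test, for example PPFIA4 at -1.25 and AK4 at -0.58. An effect of the RBP4 protein itself stays open and was not tested apart from these.

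Protein-coding genes of low abundance tended to be higher in the libraries labelled RBP4: of 971 genes in the lowest of 8 equal-width classes of log2 abundance, 286 rose and 43 fell, with a median log2 fold change of 0.47. The rise was not confined to them: of 353 lincRNA genes of that class 70 rose and 24 fell (median 0.25), and of 482 antisense genes 59 rose and 34 fell (median 0.13). The rise of protein-coding genes was part of a trend over the abundance range. Over classes 2 to 8, from low to high, their median was 0.30, 0.10, -0.043, -0.14, -0.16, -0.097 and 0.20 (6 genes in the last). In class 5, 288 of 2065 protein-coding genes rose and 1267 fell. The list tests compare a list with genes of all abundances and did not adjust for this trend. For protein-coding genes of the lowest class, GC content was argued against, as the median was 0.43 after its trend was removed. With pseudocounts of 0.1, 1 and 5 their median was 0.50, 0.47 and 0.37, so none of these choices removed the rise. A larger pseudocount pulls fold changes of low genes to 0, so this check could show only that the rise remained. Genomic DNA or unspliced RNA in the RBP4 libraries was argued against as the whole source by sense-intronic genes of the same class, with a median of -0.16 over 88 genes. Processed pseudogenes of that class had a median of -0.15 over 239 genes. As copies of other genes they can take reads of those genes, so their median cannot decide the question. A biological difference between the groups, which the design gives as the treatment, stays open as a hypothesis. These tests cover the lowest class only, so a technical source of the trend over all classes also stays open.

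A list of 18 transcripts that nonsense-mediated decay removes was tested as a hypothesis of a rise in the RBP4 libraries: 7 rose, 5 fell, the median was 0.068 and the camera p was 0.299 (0.357 with an estimated correlation), which leaves the question open. The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 7934 genes and the highest of the others 0. Each of the others mixes both groups, which puts the group difference into the spread, so this contrast follows largely from the design.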
